A study of Mus musculus with 2 samples.

How the data were processed

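Single-cell RNA was measured in liver macrophage preparations of 2 mice, 1 saline and 1 Ter119, with 1 library each. Per the labels' protocols, both mice came from the C57BL/6J strain, livers were digested, non-parenchymal cells were enriched with anti-rat IgG beads carrying antibodies to F4/80 and CD11b, and cells were stained with hashtag antibodies, pooled at equal cell number and run with 10x Genomics 3' chemistry for a target of 10000 cells. The authors deposited 1 matrix of raw UMI counts per gene and barcode for each sample, in which no barcode has under 500 UMIs. The matrices were written by Cell Ranger 6.0.2 per the file headers, whereas the submitters' processing notes list Cell Ranger 4.0.0, Scanpy 1.7.0, Seurat 3.2.3, DESeq2 1.26.0 and the genome build GRCm38.p6. How the hashtags were used to separate the mice is not given in the sources used here, hashtag counts were not analysed here, and 133 barcode sequences occur in both samples. Gene positions were taken from GENCODE vM21 on GRCm38 by gene identifier.

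From the counts, barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs. Scrublet, as in scanpy 1.11.5 with an expected rate of 0.08, called 0 of 11572 saline and 1 of 13846 Ter119 cells, which means that it did not work, and doublets were in effect not removed. The setting that keeps called doublets adds 1 Ter119 cell and so shows how far clustering almost the same cells again moves the results. Counts were scaled to 10000 per cell and log-transformed, and both samples were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with leiden (leidenalg 0.10.2) at resolution 1.0. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and edgeR 4.0.16.

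Cell filters, markers, gene lists, core genes and the rule for named genes were fixed before the data were examined. A cluster's genes were ranked, within the sample holding most of it, by CPM plus 20 over the 25th percentile of clusters plus 20, among genes with at least 50 CPM, a UMI in 20% of its cells and a fold of 1.5. The class with most markers among the top 50 genes gave the name. A cluster stayed unnamed with under 30 cells, under 3 markers, more markers of another class among its top 10 genes, a tie, or a median UMI count under 1/3 of its sample's together with none of its own markers in the top 10. Cluster 8, with a median of 1301 UMIs against 2803 in Ter119, was above that limit and kept its name without a marker in the top 10. Monocyte and dendritic classes, T and NK classes, and both endothelial classes were merged. This naming rule was set after looking at the clusters. A first version, which compared each cluster with the rest of its sample, was dropped because the Kupffer-like class it gave was unstable across settings, and by then the levels of some genes compared here, among them Clec4f, Timd4, Marco, Hmox1, Gpnmb and Cd74, had been seen in single clusters. The rule kept 9.06% of saline cells and 17.2% of Ter119 cells out of all classes. They include Ter119 cluster 2 (1808 cells), which has Kupffer markers but is led by hemoglobin genes, and saline cluster 14 (580 cells), which has Kupffer and endothelial markers.

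For each class, counts were summed per sample and expressed as CPM. Ratios of Ter119 over saline have exact conditional binomial 95% intervals, and shares have exact Clopper-Pearson 95% intervals. A value of 0 was set to a floor of 3 counts for ratios, and a share of 0 is given with the limit that 3 counts allow. PCR and cell-to-cell variation are not in these intervals, which cover counting error only. Genes with at least 20 CPM in 1 of the samples were compared by a size rule of 2-fold. The median log2 ratio of each of 20 fixed gene lists was set against 10000 random lists of the same size matched on mean expression in 20 bins, and a median outside the 2.5th to 97.5th percentile was called apart. These percentiles are no p-values over mice. No DESeq2 or edgeR test was run, since there is 1 sample per group, and edgeR gave TMM factors for an alternative scaling.

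The rule for named genes took 22 core genes, up to 4 members of each list with the largest absolute log2 ratio, and outside the lists the 10 highest and 10 lowest ratios among genes with at least 50 CPM and a UMI in at least 10% of cells of the higher sample. Outside the lists it left out mitochondrial, ribosomal, sex-linked, unnamed and receptor segment genes and genes over 5 times higher in another class of the sample in which they stood higher. Core genes and list members of the last kind, such as Il1b, Il1rn, Btg2, Stmn1 and Hbb-bs, stayed. It gave 105 genes, of which some are not reported here. Alb and Cxcl10 and the genes of unnamed clusters were mentioned after their values were seen. Lists matched all members except Itgam, Aldoa and Ahsp, which are not used here.

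The comparison was tested on simulated counts for the Kupffer-like Ter119 over saline comparison, with 6195 genes in the step. All 50 genes simulated 3-fold higher and all 50 simulated 3-fold lower passed the 2-fold rule, and 0 of 50 genes in each direction at 1.5-fold and 0 of 5995 unchanged genes did. Intervals covered the simulated ratio for 95.0% of unchanged genes, and 4 of 100 unchanged lists were called apart. The simulated counts held counting error only, which is what the intervals assume. These rates therefore check the calculation and say nothing about differences between mice, libraries or cells.

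Other settings, also fixed in advance, changed the cell filters, doublet handling, clustering resolution, genes used to cluster, definition of the Kupffer-like class, scaling, depth, low-value filter, pseudocount and matching bins. Settings chosen after seeing the data removed the highest 8% of doublet scores, added unnamed clusters with mostly Kupffer markers, left out hemoglobin genes, left out genes with a higher CPM in lymphoid cells, and left out the clusters led by Cxcl10 from saline or from both samples.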

Results

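Liver macrophages were profiled from 2 C57BL/6J mice aged 7 to 10 weeks, 1 given saline and 1 given Ter119, an antibody that binds an antigen on the surface of red cells. The treated mouse received 1 dose of 35 ug and then 10 daily doses of 10 ug, and livers were taken 24 after the last injection, a time whose unit the labels leave out. By its title, the series addresses how the uptake of red cells reprograms Kupffer cells, the resident macrophages of the liver. Non-parenchymal cells were enriched with magnetic beads for F4/80 and CD11b, and transcripts were counted by unique molecular identifiers (UMIs) in droplet-based single-cell libraries. The saline library held 18354 barcodes and 97181787 UMIs, with a median of 3523 UMIs per barcode. The Ter119 library held 25760 barcodes and 61892074 UMIs, with a median of 1854. After filtering, 11572 saline cells (median 6239 UMIs) and 13845 Ter119 cells (median 2803 UMIs) remained. With 1 mouse in each group there was no replicate check and no test between treatments. The values describe these 2 libraries, in which treatment, mouse and library cannot be told apart, and all 95% intervals cover counting error only.

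The first comparison asked which cell classes the 2 suspensions held. Kupffer-like cells, named from markers such as Clec4f, Vsig4 and Cd5l, made up 69.1% of saline cells (7992 of 11572, exact binomial interval 68.2 to 69.9%) and 33.2% of Ter119 cells (4594 of 13845, 32.4 to 34.0%). Monocyte-like or dendritic-like cells made up 4.98% of saline cells (4.59 to 5.39%) and 17.6% of Ter119 cells (17.0 to 18.3%). Endothelial-like cells made up 7.16% and 14.9%, and neutrophil-like cells 2.99% and 6.26%. Erythroid-like cells, led by hemoglobin genes, were 722 Ter119 cells (5.21%, 4.85 to 5.60%) and 0 of 11572 saline cells, which allows a share of up to 0.0259%. Proliferating cells made up 5.59% of saline and 3.72% of Ter119 cells, B-like or plasma-like cells 0.830% and 0.650%, and T-like or NK-like cells 0.328% and 1.257%. Unnamed clusters held 9.06% of saline cells and 17.2% of Ter119 cells. The naming treated mixed clusters unlike: Ter119 cluster 7 (866 cells) counted as endothelial-like although it had Cd5l at 4257 CPM and Hmox1 at 5110 CPM, against 5888 and 6624 CPM in Kupffer-like cluster 1, and saline cluster 14 (580 cells), with Kupffer and endothelial markers, stayed unnamed. When clustering was run again with 1 Ter119 cell more, the called doublet, the saline endothelial-like share was 12.3%, against 14.9% in Ter119. A limit of 5% mitochondrial UMIs left 2080 saline and 7864 Ter119 cells. In these, saline and Ter119 had 3.22% and 10.0% endothelial-like, 12.8% and 24.0% monocyte-like or dendritic-like and 6.59% and 8.61% neutrophil-like cells. The order of proliferating cells turned (0.673% and 3.12%), with 14 such cells in saline. That of B-like or plasma-like cells turned too (0.337% and 0.649%), but saline had 7 and the intervals overlapped (0.135 to 0.692% and 0.483 to 0.852%). The order of proliferating cells also turned without the highest 8% of doublet scores, where a saline cluster of 602 cells lost its proliferating name to a tie with Kupffer markers. No erythroid-like class was named at resolution 0.5 or with at least 2000 UMIs. The enrichment used anti-rat IgG beads, and whether these also bound red cells that carried the injected antibody was not tested, which leaves open what the erythroid-like share and the hemoglobin RNA of the Ter119 suspension reflect. The enrichment can set part of all these shares, and the order of the Kupffer-like shares turned when cells were classed by their own markers (5.46% in saline and 7.01% in Ter119). That rule asked for at least 2 Kupffer markers and at most 2 markers of each other class, a limit that is harder to meet with more UMIs. It left 94.5% of saline cells and 93.0% of Ter119 cells unnamed. In the main setting, the Kupffer-like class was made of clusters 0, 3, 4 and 12 in saline and clusters 1, 8 and 32 in Ter119, each with at most 7 cells of the other library, so that a cluster may be a library and not a cell state. Clusters 8 and 32 had 3 Kupffer markers among their top 50 genes and 0 among their top 10. Cluster 8 (790 cells, median 1301 UMIs) was led by Fth1, Il18 and Ftl1, and clusters 12 and 32 by Cxcl10.

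The main comparison asked how Kupffer-like cells differed between the mice, from counts summed over 7992 saline cells (58525008 UMIs) and 4594 Ter119 cells (15644180 UMIs). Genes of heme and iron handling were among those that stood higher in Ter119. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1 (ENSMUSG00000005413, GRCm38 chromosome 8, 75093621 to 75100589), stood at 1000 CPM (UMI counts scaled to the summed total of the class) in saline and 6620 CPM in Ter119, a ratio of 6.62 (6.55 to 6.69). The ferritin chains that store iron followed, with ratios of 5.91 for Fth1 (5770 and 34112 CPM) and 2.78 for Ftl1 (7327 and 20369 CPM). Spic, a transcription factor of iron-recycling macrophages (ENSMUSG00000004359, chromosome 10, 88674772 to 88685015), had a ratio of 3.82 (3.70 to 3.94). The iron exporter Slc40a1 did not share this difference, at 4435 CPM in saline and 3896 CPM in Ter119 (ratio 0.878, 0.871 to 0.886), and its log2 ratio turned to 0.08 and 0.06 under the other scalings. Cd163, the receptor for hemoglobin bound to haptoglobin (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), stood 25.6 times lower in Ter119 (858 and 33.6 CPM). Of 20 measured members of the heme and iron list, 6 were at least 2-fold higher and 1 at least 2-fold lower, and the list's median (log2 ratio -0.19) lay at the 25.4th percentile of 10000 matched random lists, not apart from them, and had the opposite sign under median-of-ratios factors (0.08).

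**Figure D1:**
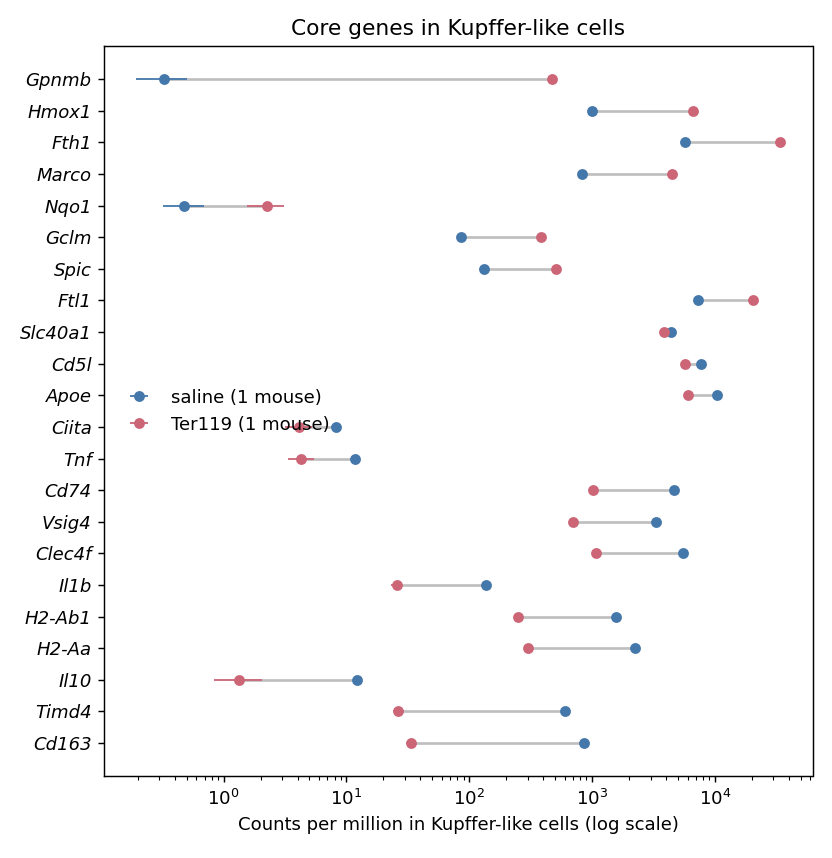
CPM (horizontal, log scale) of 22 core genes in Kupffer-like cells of 1 saline mouse and 1 Ter119 mouse; bars are exact 95% intervals for counting error only, and grey lines join the 2 values of a gene. Gpnmb, Hmox1, Fth1 and Marco stand highest in Ter119 relative to saline, and Cd163, Timd4 and Il10 lowest.

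Targets of NRF2, the transcription factor of the oxidative stress response, were also higher. Of 19 measured members, 7 were at least 2-fold higher and 0 lower, with a list median of 0.90 above all 10000 matched lists (percentile 100). Gstm1 had a ratio of 7.63, Mgst1 5.82, Me1 4.25 and Gclm, a subunit of the enzyme that makes glutathione's precursor, 4.43 (4.27 to 4.60). Nqo1 was counted 28 times in saline and 35 times in Ter119, a ratio of 4.68 with a wide interval (2.76 to 7.98).

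The set with the largest median among lists other than hemoglobin and related erythroid transcripts was that of lipid-associated macrophages, of which 12 of 15 measured members were at least 2-fold higher in Ter119 and 0 lower (median log2 ratio 2.99, percentile 100). Gpnmb, a transmembrane glycoprotein of such macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), was counted 19 times in saline and 7345 times in Ter119, a ratio of 1446 (925 to 2404). Cd63 had a ratio of 106, the fatty acid-binding protein gene Fabp5 104 and Spp1, which encodes osteopontin, 72.7, although Spp1 was more abundant in Ter119 lymphoid cells (59.2 CPM) than in Kupffer-like cells (37.3 CPM). Cholesterol synthesis genes were higher as a list (5 of 11 at least 2-fold, median 0.90, percentile 100), with ratios of 4.36 for Fdps, 2.49 for Cyp51 and 2.40 for Msmo1. Glycolysis genes were higher too (8 of 15 at least 2-fold and 1 lower, median 1.01, percentile 100), with Slc16a3 at 3.55, Gapdh at 3.25, Pgam1 at 3.02 and Eno1 at 2.56. Oxidative phosphorylation genes had a smaller median of 0.36 (percentile 99.8) with 0 of 20 members past 2-fold, and Cox5b at 1.67 and Sdhb at 1.66. That median was 0.08 when cells were classed by their own markers, within the range of matched lists.

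Genes that mark Kupffer cells stood lower as a list. Of 24 measured members, 13 were at least 2-fold lower and 2 at least 2-fold higher (median -1.08, percentile 0). Several members, Clec4f, Vsig4, Timd4 and Marco among them, were also markers by which clusters were named, so the list is not independent of the class. Timd4, a receptor for dying cells (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332), had 598 CPM in saline and 26.5 CPM in Ter119, 22.6 times lower (20.5 to 24.9). C6 was 16.7 times lower, Xlr 12.6 times lower, the lectin Clec4f (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187) 5.10 times lower (5484 and 1075 CPM) and the complement receptor Vsig4 4.70 times lower (3295 and 702 CPM). Cd5l differed less, with a ratio of 0.747 (7664 and 5727 CPM), and its sign turned when cells were classed by their own markers. The 2 members that were higher were Spic and the scavenger receptor Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), which had 832 CPM in saline and 4489 CPM in Ter119 (ratio 5.40, 5.33 to 5.46). The monocyte-derived list was lower as well (4 of 6 at least 2-fold lower, median -1.99, percentile 0), with Plac8 8.78 times, Ms4a4c 5.75 times and Fn1 5.09 times lower. Plac8 was more abundant in lymphoid cells (990 CPM in saline) than in Kupffer-like cells (499 CPM), and without genes that stood higher in lymphoid cells the median of the monocyte-derived list turned to 0.48.

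Antigen presentation genes were lower in Ter119 Kupffer-like cells. Of 9 measured genes of the MHC class II list, which present antigen to CD4 T cells, 6 were at least 2-fold lower and 0 higher (median -2.03, percentile 0). H2-Eb1 stood 7.64 times lower, H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) 7.41 times (2227 and 301 CPM), H2-Ab1 6.34 times (1582 and 250 CPM) and Cd74, the invariant chain, 4.56 times (4657 and 1021 CPM). Ciita, the master regulator of these genes, was scarce, at 8.22 CPM and 4.09 CPM (ratio 0.498, 0.377 to 0.647), and more abundant in lymphoid cells (49.2 and 19.7 CPM). MHC class I genes had a median of -0.74 (2 of 14 at least 2-fold lower, percentile 0.05), with H2-Q7 5.39 times and H2-Q4 3.06 times lower and B2m at a ratio of 0.521. Interferon-stimulated genes had a median of -0.78 (10 of 30 at least 2-fold lower and 0 higher, percentile 0), with Irf7 4.71 times, Oasl2 2.93 times, Usp18 2.62 times and Zbp1 2.59 times lower. H2-Aa was more abundant in the lymphoid cells of both samples (3216 and 1481 CPM) than in Kupffer-like cells, and the MHC class II median was -0.67 over the 3 genes left without genes of this kind, at the 11.6th percentile and no longer apart. B-like or plasma-like cells, part of the lymphoid cells, held more Cd74 (9072 and 4101 CPM) than Kupffer-like cells did. Leaving out such genes therefore does not separate free RNA from genes that lymphoid cells express.

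Inflammatory cytokines and NF-kB targets were lower as a list (4 of 13 at least 2-fold lower and 2 higher, median -0.67, percentile 0.34). Il1b stood 5.31 times lower (136 and 25.7 CPM), Nfkbiz 3.55 times and the inflammasome gene Nlrp3 2.83 times, while the chemokine gene Ccl9 had a ratio of 4.05. Neutrophils held far more Il1b than Kupffer-like cells, at 1986 CPM in saline and 221 CPM in Ter119, and so differed in the same direction (ratio 0.111). Most of these neutrophils came from unlike clusters, 20 in saline (Il1b at 1946 CPM) and 16 in Ter119 (26.0 CPM). Cluster 18, with 38 saline and 357 Ter119 cells, held Il1b at 2334 and 448 CPM. Tnf was low in both samples, at 11.8 and 4.28 CPM (ratio 0.363, 0.278 to 0.467), and so was Il10, at 12.3 and 1.34 CPM (ratio 0.109, 0.0673 to 0.169). Saline cluster 12, led by Cxcl10, held 8.23% of the saline Kupffer-like cells but 69.0% of their Tnf counts and 40.2% of their Il1b counts. Without that cluster the list's median was -0.29 and the log2 ratio of Tnf was 0.07, but Ter119 cluster 32, also led by Cxcl10, held 40.3% of the Ter119 Tnf counts. Without both clusters the list's median was -0.36, at the 19.7th percentile, and Tnf still stood lower (-0.63). Immediate early and heat shock genes, which can respond to cell isolation, had a median of -0.68 (7 of 15 at least 2-fold lower and 0 higher, percentile 0.24), with Fos 3.49 times, Btg2 2.60 times, Ier2 2.52 times and Zfp36 2.31 times lower, and this median was also no longer apart without those clusters (-0.52).

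Other lists differed less or by single members. The list of targets of LXR, a sterol-sensing receptor, and of cholesterol efflux had a median of -0.50 (2 of 14 at least 2-fold lower and 1 higher, percentile 1.66), with Apoc1 30.8 times and Pltp 3.33 times lower, Apoe at a ratio of 0.572 (10518 and 6020 CPM) and Scd2 at 3.53. It was no longer apart among cells classed by their own markers (-0.21). Lysosome genes were not apart (4 of 26 at least 2-fold higher and 0 lower, median 0.07, percentile 74.6), although Cd63, Atp6v0d2 (ratio 53.6), Ctsd (2.53) and Psap (2.25) were higher. Opsonin and scavenger receptors (3 of 25 higher and 3 lower, median -0.34, percentile 4.46) were not apart either, with Gas6 at a ratio of 3.85. Nor were anti-inflammatory genes (2 of 13 higher and 3 lower, median -0.33, percentile 19.7), with Pparg at 5.08 and Cd200r1 at 3.23 against Il1rn at 0.111 and Arg1 at 0.228. ATF4 and endoplasmic reticulum stress genes (0 of 10 past 2-fold, median -0.34, percentile 16.2) and proliferation genes (1 of 6 higher and 0 lower, median 0.13, percentile 93.9) were not apart, with Herpud1 at 0.539 and Stmn1 at 2.27. All 5 measured erythroid transcripts were higher in Ter119 (median 7.15, percentile 100), but Hbb-bs was more abundant in Ter119 lymphoid cells (57427 CPM) than in Kupffer-like cells (11358 CPM). Likewise, H2-Ab1, H2-Eb1, Cd74, H2-Q7, H2-Q4, Ms4a4c, Fn1, Btg2, Ier2, Zfp36, Stmn1 and Herpud1 were more abundant in lymphoid than in Kupffer-like cells of the sample in which the Kupffer-like level stood higher.

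**Figure D2:**
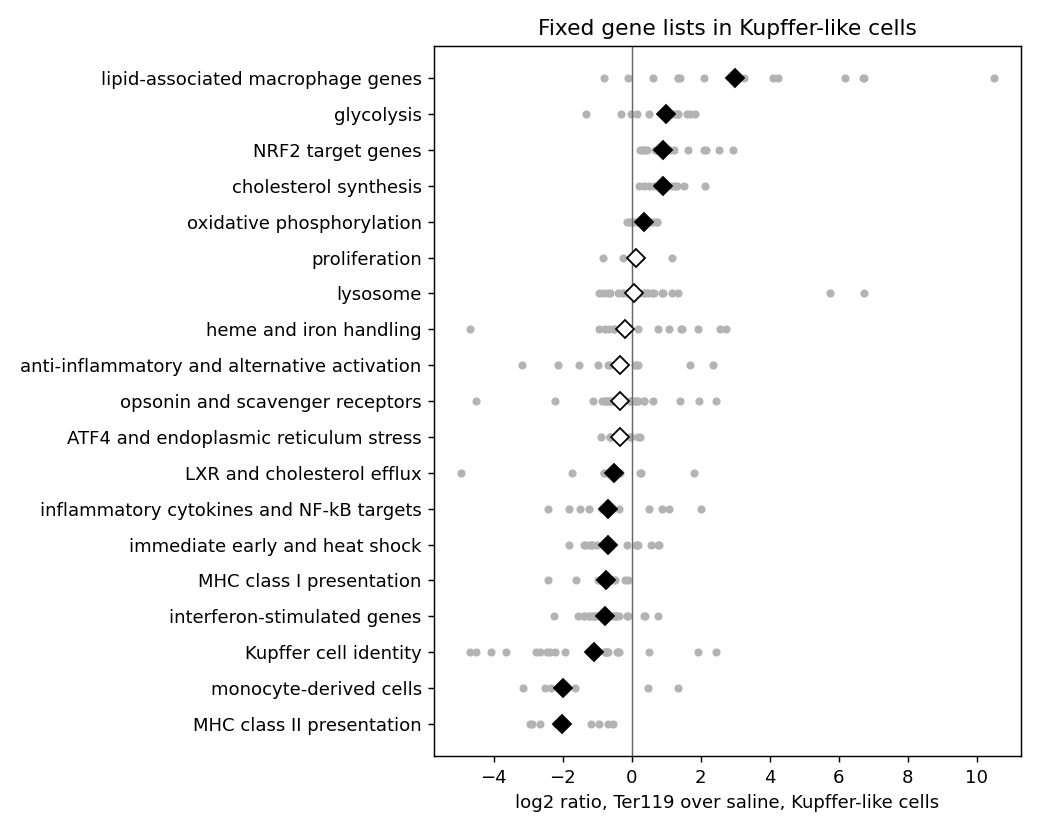
Log2 ratio of Ter119 over saline in Kupffer-like cells (horizontal) for 19 fixed gene lists (vertical), with a grey point for each measured member and a diamond at the list's median, filled where the median lies outside the central 95% of matched random lists. Lipid-associated macrophage genes have the highest median (2.99) and MHC class II genes the lowest (-2.03); erythroid transcripts (7.15) are left off.

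By size alone, 249 of 6375 genes with at least 20 CPM in 1 of the samples were at least 2-fold higher in Ter119 and 594 at least 2-fold lower, so that 29.5% of these genes were higher. This split depended on the scaling, with 405 higher and 327 lower (55.3% higher) under median-of-ratios factors and 383 and 336 (53.3%) under TMM factors. The median log2 ratio of all genes over 20 CPM was -0.22 with CPM, and 0.07 and 0.05 with those factors, a shift of the median by 0.29 and 0.27. Relative to the all-gene median, the heme and iron list (-0.19) stood level, and the lipid-associated macrophage and MHC class II lists (2.99 and -2.03) stood far to either side. Outside the lists, the genes with the highest ratios were Lrrc14b (689), Syngr1 (492), Nxpe5 (105), Lgals1 (103), Sort1 (79.0), Ddit4 (16.7), Ccr3 (11.0), Cmbl (9.70), Ptafr (9.28) and Npl (8.996). Lrrc14b and Syngr1 were each counted 8 times in saline, and Lgals1 was more abundant in lymphoid cells of both samples (331 and 706 CPM) than in Kupffer-like cells (5.14 and 530 CPM). Among the lowest were the B cell chemoattractant Cxcl13, counted 20503 times in saline and 2 times in Ter119 (ratio 0.000365, 0.0000442 to 0.00132), Gbp2b (116 times lower), the complement genes C4b (35.6 times) and C2 (26.3 times), Tmem176b (25.7 times), Serpina3k (19.2 times), Fabp1 (17.1 times), Tmem176a (16.6 times) and Slc1a2 (16.6 times). Serpina3k and Fabp1 are abundant in hepatocytes, and the hepatocyte transcript Alb stood at 1591 CPM in saline and 244 CPM in Ter119 Kupffer-like cells.

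The third comparison asked whether these differences were spread over many cells, from the share of Kupffer-like cells with a UMI after thinning each cell to 1000 UMIs. The share in lymphoid cells, which should lack most of these genes, served as background (134 saline and 264 Ter119 cells, median 5297 and 2106 UMIs, against 6806.5 and 3357.5 in Kupffer-like cells). Hmox1 was seen in 49.5% of saline cells (48.4 to 50.6%) and 97.8% of Ter119 cells (97.3 to 98.2%), with 18.7% and 68.2% in lymphoid cells. Gpnmb was seen in 0.0375% and 31.8% (30.4 to 33.1%), with 0 of 134 and 13.6% in lymphoid cells, a count of 0 that allows up to 2.24%. Timd4 was seen in 42.4% (41.3 to 43.5%) and 2.26% (1.85 to 2.74%), with 9.70% and 0 of 264, which allows up to 1.14%. Clec4f was seen in 98.1% and 51.8%, with 53.7% and 22.3% in lymphoid cells. Marco was seen in 40.4% and 84.2% (17.9% and 63.6% in lymphoid cells), Spic in 12.0% and 38.8% (2.99% and 15.5%) and Slc40a1 in 97.0% and 94.7% (41.0% and 50.8%). Cd74 was seen in 93.4% of saline cells and 43.2% of Ter119 cells, against 85.1% and 60.6% of lymphoid cells. B-like or plasma-like cells held Cd74 at 9072 CPM in saline and 4101 CPM in Ter119, so the lymphoid share is no background for this gene. In Ter119, Cd74 stood at 1021 CPM in Kupffer-like cells and 687 CPM in neutrophils. Unthinned shares were 88.5% and 99.7% for Hmox1, 0.238% and 60.0% for Gpnmb, 86.8% and 5.94% for Timd4, 99.6% and 72.9% for Clec4f, 75.8% and 95.2% for Marco, 49.1% and 72.4% for Spic, 99.4% and 98.1% for Slc40a1, and 99.2% and 67.0% for Cd74. In lymphoid cells they were 44.0% and 87.5% for Hmox1, 2.24% and 26.9% for Gpnmb, 39.6% and 1.14% for Timd4, 89.6% and 36.0% for Clec4f, 45.5% and 81.1% for Marco, 18.7% and 30.7% for Spic, 82.1% and 72.7% for Slc40a1, and 97.8% and 68.2% for Cd74.

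The fourth comparison asked whether other classes differed in the same lists. NRF2 targets were higher than matched lists in endothelial-like (median 0.94), monocyte-like or dendritic-like (0.86), neutrophil-like (0.66) and proliferating cells (0.73), and lipid-associated macrophage genes in all 4 as well (1.59, 0.98, 1.43 and 2.17). MHC class II genes were lower in all 4 (-0.82, -0.75, -1.63 and -1.83). They were no longer apart in endothelial-like (-0.25) and neutrophil-like cells without the highest 8% of doublet scores, in endothelial-like cells with at least 2000 UMIs, or in proliferating cells with clustering without listed genes. Kupffer identity genes were lower in endothelial-like (-0.81), neutrophil-like (-1.12) and proliferating cells (-1.16), but without the highest doublet scores they were no longer apart in endothelial-like or neutrophil-like cells (-0.39 in the latter). Kupffer-derived RNA was present in these classes: neutrophils carried Kupffer identity genes at a median of 53.9% of the Kupffer-like level in saline and 49.9% in Ter119, and endothelial-like cells at 37.0% and 56.5%. The proliferating class was close to Kupffer-like cells. Saline cluster 13 had Clec4f at 4422 CPM and Cd5l at 6368 CPM, against 5598 and 7957 CPM in Kupffer-like cluster 0. Ter119 cluster 15 had Cd5l at 4662 CPM and Hmox1 at 5373 CPM, against 5888 and 6624 CPM in Kupffer-like cluster 1. Its list medians therefore do not stand for another cell type. The Ter119 over saline ratios in neutrophils were close to those in Kupffer-like cells for Marco (5.35 and 5.40), Clec4f (0.187 and 0.196) and Hmox1 (5.94 and 6.62), and nearer to 1 for Fth1 (2.497 and 5.91), Cd63 (4.15 and 106) and Fabp5 (8.62 and 104). For Gpnmb they were 142 and 1446, but the neutrophil ratio rests on 2 saline counts and the intervals overlap (39.1 to 1176 and 925 to 2404). Part of these levels can be Kupffer-derived RNA, so that the list medians of other classes are not read as changes of those cells. These classes too came mostly from different clusters in the 2 samples, such as 17 and 19 in saline and 5 and 7 in Ter119 for endothelial-like cells, and 13 and 15 for proliferating cells. Neutrophil-like cells were mostly cluster 20 in saline (306 cells, Camp at 0.889 CPM) and cluster 16 in Ter119 (506 cells, Camp at 23887 CPM). Interferon-stimulated genes had a median of -1.43 in neutrophils, with 24 of 30 members at least 2-fold lower, against -0.55 in monocyte-like or dendritic-like and -0.72 in proliferating cells, and were not apart in endothelial-like cells (-0.28). The neutrophil median thus compares mostly unlike clusters.

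**Figure D3:**
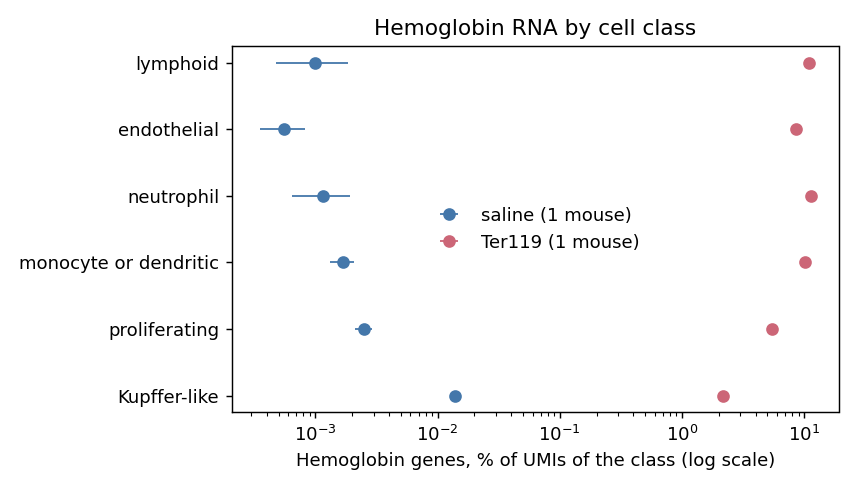
Share of UMIs from 4 hemoglobin genes (horizontal, log scale) in 6 cell classes (vertical) of 1 saline and 1 Ter119 mouse, with exact binomial 95% intervals for counting error only. In saline the Kupffer-like cells have the highest share (0.0140%), and 80 cells hold 96.0% of these UMIs. Their share in Ter119 (2.16%) leaves out a cluster with Kupffer markers that stayed unnamed because hemoglobin genes led it. That share is 7.86% over all clusters with mostly Kupffer markers, which leave out erythroid-like cluster 10.

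Hemoglobin RNA separated the libraries in every class. Hemoglobin genes gave 0.0268% of all saline UMIs and 23.3% of all Ter119 UMIs, and over 50% of the UMIs in 5 saline and 7156 Ter119 barcodes (27.8%). In Ter119 the share was 11.0% in lymphoid cells, 11.3% in neutrophils, 8.48% in endothelial-like cells, 5.44% in proliferating cells and 7.86% in all clusters with mostly Kupffer markers. It was 2.16% in the named Kupffer-like class, from which the naming rule keeps out cluster 2, led by hemoglobin genes. Both Kupffer values leave out erythroid-like cluster 10 (51.3%), which also had Cd5l at 2266 CPM. These pooled shares rest mainly on part of the cells, with a mean of 296 and a median of 15 hemoglobin UMIs per lymphoid cell. Means and medians were 301 and 16 in neutrophils, 220 and 14 in endothelial-like cells, and 73.6 and 15 in the named Kupffer-like class. The median kept Ter119 cell had 1.05% of its UMIs from hemoglobin genes. Barcodes over the mitochondrial limit of 15% made up 25.3% of saline and 5.96% of Ter119 barcodes that had passed the other filters.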

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

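All tests in this part were chosen after the results were seen, except the share of hemoglobin UMIs in the richest 1% of saline cells, the comparison of cells with and without Timd4, and the ratio of Kupffer-like to neutrophil levels in saline, whose bounds were written first. Several signals lay in cells outside the comparisons, at levels above saline. In Ter119, 5410 barcodes with at least 1000 UMIs but under 500 genes had over 50% of their UMIs from hemoglobin genes, against 3 in saline. Unnamed cluster 2, with Kupffer markers and hemoglobin genes leading, held 1808 Ter119 cells and 0 saline cells. Cluster 21, with Kupffer markers and neutrophil genes leading, held 250 and 0 cells. Cluster 28, led by the neutrophil granule genes Camp and Ngp, held 147 and 1 cells, and cluster 34, led by the erythroid genes Car2 and Slc4a1, held 72 and 1 cells. Proliferation genes went opposite ways in 2 classes, higher in Ter119 neutrophils (median log2 ratio 1.02) and lower in Ter119 proliferating cells (-0.47), and the difference between the classes was not tested. The neutrophils were mostly cluster 20 in saline (Mki67 at 12.5 CPM, Camp at 0.889 CPM) and cluster 16 in Ter119 (45.7 and 23887 CPM). Their median thus compares mostly unlike clusters.

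Hemoglobin RNA outside erythroid cells was the first pattern weighed. In Ter119, its share of UMIs in lymphoid cells was 1.40 times that in all clusters with mostly Kupffer markers. These clusters leave out erythroid-like cluster 10 (722 cells, 51.3% hemoglobin UMIs). Hemoglobin genes led that cluster, but it also had Cd5l at 2266 CPM and Marco at 1872 CPM. Since the naming sorted such cells by the quantity compared, the ratio cannot decide on free RNA. Whether macrophages also held red cell RNA of their own stays open. Over all clusters with mostly Kupffer markers, again without cluster 10, the mean hemoglobin UMIs per cell were 0.981 times those of lymphoid cells but the median 1.73 times. In the named Kupffer-like class, which leaves out cluster 2, the median was 15 UMIs per cell, as in lymphoid cells. In saline, the share in Kupffer-like cells was 13.9 times that in lymphoid cells (7.58 to 29.1), but this ratio does not decide on free RNA. Its interval takes UMIs as independent, and the lymphoid share rests on 10 UMIs in 134 cells. A hemoglobin UMI was seen in 5.09% of Kupffer-like cells and 7.46% of lymphoid cells. In saline, 80 cells held 96.0% of the hemoglobin UMIs of Kupffer-like cells, as a red cell in the same droplet would give, whether beside the macrophage or inside it. The 134 lymphoid cells are too few to hold many cells of this kind. Larger saline classes had lower means than the 1.03 hemoglobin UMIs per Kupffer-like cell. These were 0.0277 in 829 endothelial-like, 0.0434 in 346 neutrophil-like, 0.148 in 576 monocyte-like or dendritic-like and 0.233 in 647 proliferating cells. Among these classes the UMIs were thus concentrated in Kupffer-like cells of 1 library, and the cause of that was not tested.

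The lower Kupffer identity genes were the second pattern. Plain dilution by free RNA or other cells would lower all members alike, but 12 of 24 members had a ratio whose whole interval lay over 2 times from the list's median ratio. Among Ter119 Kupffer-like cells, the 273 with a Timd4 UMI had 2.07 times the summed level of Clec4f, C6, Cd163 and Folr2 (1.99 to 2.16), an interval that takes in the bound of 2 set beforehand, but Clec4f stood at 1849 CPM in them and 1020 CPM in the others, against 5484 CPM in saline and a background of 533 CPM in Ter119 neutrophils. A mixture of cells that keep and cells that lack these genes stays open, since free RNA adds to these levels and 1.14% of Ter119 lymphoid cells also had a Timd4 UMI, as do the origin of the cells and a difference between mice or libraries, which the design cannot separate from treatment.

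The lower MHC class II genes were the third pattern. Free RNA from other cells rich in MHC class II could have raised the saline level, but the test did not decide: the list's median ratio of Kupffer-like over neutrophil level in saline was 1.62, between the bounds of 1.2 and 2 set beforehand, and was 1.86 for Kupffer identity genes. An equal shift of all genes is argued against, since the list's median lay at -1.81 from that of all genes and outside the range of matched lists. It stayed outside under both other scalings, but these move the list and its matched lists together and so add no support. MHC class II genes lower in all cells of the library cannot be told apart from a difference in Kupffer-like cells, since the log2 ratios in Kupffer-like cells were lower than in monocyte-like or dendritic-like cells by a median difference of -0.73, with quartiles of -1.91 and -0.44. A lower expression in Kupffer-like cells after Ter119 remains a hypothesis.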

How the results depend on the processing

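The alternatives without the highest 8% of doublet scores, with unnamed Kupffer-marker clusters, without hemoglobin genes, without genes higher in lymphoid cells and without the clusters led by Cxcl10 were chosen after the results were seen. No paired analysis was possible because each group has 1 sample. Of 416 list medians in Kupffer-like cells under alternatives, 392 kept their side of the middle of the matched lists and their place inside or outside the range of these. Median-of-ratios and TMM factors move a list and its matched lists together, so under both a place could change only through the filter of 20 CPM. By sign, the medians of heme and iron (-0.32 to 0.20), lysosome (-0.093 to 0.43), proliferation (-0.20 to 0.46) and ATF4 genes (-0.56 to 0.013) went either way. Those of Kupffer identity (-1.24 to -0.82), lipid-associated macrophage genes (2.17 to 3.34), NRF2 targets (0.65 to 1.17), glycolysis (0.92 to 1.28), cholesterol synthesis (0.70 to 1.31), MHC class I (-0.92 to -0.48) and interferon-stimulated genes (-1.01 to -0.51) stayed apart in every alternative run. Of 1757 log2 ratios of named genes, 1113 lay within the counting interval of the main value, 642 moved, and of genes at least 2-fold apart 1 changed sign, Tnf, to 0.077 with called doublets kept and to 0.074 without the saline cluster led by Cxcl10. Since that cluster holds most saline Tnf counts, its leaving accounts for the second. Without such clusters in both samples Tnf was at -0.63. Of named genes under 2-fold apart, Slc40a1 (0.13), Cd5l (0.12) and Dnajb9 (0.038) changed sign by markers per cell, and Slc40a1 (0.080 and 0.058) and Mcm3 (up to 0.026) under both other scalings. Among the core genes, depth limits Nqo1, Tnf, Il10 and Ciita, with under 100 counts in Ter119. Other ratios also rest on few counts in 1 sample, such as those of Cxcl13 (2) and Gbp2b (37) in Ter119. In saline, Lrrc14b and Syngr1 had 8 counts each and Gpnmb 19.

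Genes at least 2-fold higher and lower were 405 and 327 with median-of-ratios factors, 383 and 336 with TMM factors, 104 and 181 at 100 CPM or more, and 396 and 1169 at 5 CPM or more, where the filter sets the number of genes. With called doublets kept, which adds 1 Ter119 cell and clusters almost the same cells again, the medians of inflammatory genes (-0.30) and immediate early genes (-0.38) were no longer apart. Without the saline cluster led by Cxcl10 they were -0.29 and -0.49, and without such clusters in both samples -0.36 and -0.52, no longer apart. Without genes higher in lymphoid cells, MHC class II (-0.67), LXR (-0.40) and immediate early genes (-0.25) were no longer apart, and monocyte-derived genes turned to 0.48. By markers per cell, LXR (-0.21), oxidative phosphorylation (0.077) and monocyte-derived genes (-0.58) were no longer apart, and lysosome genes (0.43) were. LXR genes were at -0.61 and no longer apart, and opsonin receptors at -0.51 and apart, with at most 5% mitochondrial UMIs. At 100 CPM or more, anti-inflammatory genes (-0.62) and opsonin receptors (-0.40) were apart and monocyte-derived genes (-0.57) were not. At 5 CPM or more, monocyte-derived genes (-0.48) were not apart and proliferation genes (0.14) were, as the latter were at resolution 0.5 (0.27), with clustering without listed genes (0.36) and as a mean over cells (0.19). Apart from the filters on CPM and the Cxcl10 clusters, the cause was not tested.

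The Kupffer-like share of saline cells was 74.1% with unnamed clusters included, 68.2% at resolution 2.0, 70.4% with at least 2000 UMIs, 70.0% at 5% mitochondrial UMIs, 64.0% with called doublets kept, 76.7% without the highest 8% of doublet scores and 5.46% by markers per cell. In Ter119 it was 48.0%, 41.1%, 36.6%, 43.6% and 50.1% in the same settings other than called doublets kept and markers per cell, 28.9% at resolution 0.5, 34.9% with clustering without listed genes and 7.01% by markers per cell. The cause was not tested.

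Unthinned shares of Kupffer-like cells with a UMI, saline then Ter119, were 88.5% and 99.7% for Hmox1, 99.4% and 98.1% for Slc40a1, 49.1% and 72.4% for Spic, 75.8% and 95.2% for Marco, 86.8% and 5.94% for Timd4, 99.6% and 72.9% for Clec4f, 99.2% and 67.0% for Cd74 and 0.238% and 60.0% for Gpnmb, as more UMIs per cell give.

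In other classes, 12 of 580 medians changed side of the middle of their matched lists. In endothelial-like cells these were opsonin receptors at resolution 0.5 (-0.44) and with called doublets kept (-0.45), heme and iron genes with called doublets kept (-0.20) and MHC class II genes without the highest 8% of doublet scores (-0.25). In monocyte-like or dendritic-like cells, identity genes were at 0.032 with at least 2000 UMIs, 0.28 at 5% mitochondrial UMIs and 0.0295 without the highest 8% of doublet scores. In neutrophils, monocyte-derived genes were at -0.18 at resolution 0.5 and identity genes at -0.39 without the highest 8%. In proliferating cells, monocyte-derived genes were at 0.74 at resolution 2.0, 0.74 with called doublets kept and 0.63 with clustering without listed genes. The cause was not tested.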

Other observations

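The tests cited here were chosen after the results were seen, except the comparison by Timd4. The Ter119 suspension held cells with genes of immature blood cells, among them clusters 28 and 34, in which saline had 1 cell each. The 147 Ter119 cells of cluster 28 had Camp at 46037 CPM, Ngp at 32188 CPM and Elane, an early granule gene, at 1244 CPM, together with the proliferation gene Mki67 at 608 CPM. The 72 cells of cluster 34 had Car1 at 392 CPM and the erythroid transcription factor gene Klf1 at 149 CPM, with Mki67 at 594 CPM. Granule genes were also high in named clusters. Neutrophil-like cluster 16 had Camp at 23887 CPM and Ngp at 21275 CPM in 506 Ter119 cells. Monocyte-like or dendritic-like cluster 24 had Elane at 885 CPM in 156 Ter119 cells and 6.11 CPM in 38 saline cells. Both samples had a Kupffer-like cluster led by Cxcl10, cluster 12 with 658 saline cells (424 CPM of Cxcl10 and 80.1 CPM of Tnf) and cluster 32 with 89 Ter119 cells (781 CPM and 70.0 CPM).

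Ter119 Kupffer-like cells with and without a Timd4 UMI (273 and 4321 cells, median 3804 and 3330 UMIs) differed most in Cd163 (8.73 times higher with Timd4, 7.28 to 10.4) and C6 (5.13 times, 4.44 to 5.91) of the 12 genes compared. Marco was 1.84 times higher, Gpnmb was at 0.753 and Fabp5 at 0.7501 of the level in cells without Timd4, and Hmox1 (0.985) and Spic (0.983) lay within counting error of equal levels. Part of the Timd4 UMIs may be background, seen in 1.14% of Ter119 lymphoid cells. A hypothesis beside the ratio of 2.07 for the identity genes, a test that did not settle a mixture, is that high Hmox1 and Spic may be shared by cells that differ in identity genes; lineage tracing or a second Ter119 mouse would be needed to test it.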
